A study of Mus musculus with 14 samples.

How the data were processed

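The deposited table holds UMI counts, as whole numbers, of 21205 genes in single cells of 14 plates. Per the labels' protocols, single cells were sorted by FACS into 96-well plates with spike-in RNA, and well-specific template-switching oligonucleotides tagged the 5′ end of each transcript with a UMI. Per the submitters' processing notes, the sources used here name bcl2fastq, STAR 2.5.3a, HTSeq 0.9.1 and build GRCm38, and the deposited cell annotation marks 0 of the cells as filtered out. The filters that preceded it are not given in the sources used here. A second deposited file gives each cell's plate, its genotype and, for 458 cells, the protein stainings recorded during the sort, with the fraction of mitochondrial and spike-in UMIs as the authors computed it. Plate and genotype matched the labels for all 14 plates, and the sum of counts of each cell equalled the total the authors deposited for it. A count is at most 1024 per gene and cell, the number of different UMIs of 5 bases, and the median non-zero count is 64, so a transcript near that number in a cell is understated. No doublet caller was run, because cells were sorted singly into wells and the authors' annotation marks 0 wells as holding several cells. No cell was removed; 48 cells with under 500 genes were left out only in an alternative.

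Cells are not replicates. UMI counts were summed over the cells of each plate, and the plate, which is 1 tumour of 1 mouse, was the replicate. Replicate numbers follow the order of the accessions. Genes were kept by filterByExpr (16203 over all cells), scaled by TMM and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, in a fit of all 14 plates with 4 groups that share one estimate of the spread. The single Ikbkb control plate is assumed to vary like the other groups. Adjusted p values are by Benjamini-Hochberg with a threshold of 0.05, and edgeR tests are two-sided. CPM are counts per 1000000 UMIs of the plate after TMM scaling. Gene lists were tested with camera of limma 3.58.1 on voom values, with the inter-gene correlation preset at 0.01, adjusted over the 22 lists that had 5 or more kept genes. Beside it stand camera with an estimated correlation, which called none of the lists over all cells, and fry, which tests whether a list's genes move one way on balance and does not compare the list with other genes. The numbers of list members higher or lower come from the edgeR fit, and list medians from the voom values. The stress list of the Irf1 comparison has a median above 0 and most members below 0 for that reason. In the Irf1 comparison fry called MHC class I as higher (adjusted p = 4.58e-09), while 18 of its 23 members were lower.

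Cells were clustered with scanpy 1.11.5 (counts per 10000, 2000 variable genes, 15 components, 15 neighbours, Leiden resolution 1). Clusters were named by the markers fixed in advance, and the remaining clusters were compared by number. A state was tested within plates that had at least 10 of its cells. Because cells were sorted, shares of states can be set by the gate, and 184 cells lay outside the cDC1-like clusters. A second clustering left out 53 genes, namely the IRF1 target list and the genes called in mature cells; 129 of its 130 mature cells were also mature in the first. Shares, depth, list levels and stainings were compared with exact permutation tests of plate values, two-sided, and intervals of single shares are exact binomial ones that cover counting error only. Positions come from the GRCm38 annotation; 21042 of the 21205 symbols matched it. The stainings were compared on the arcsinh scale as plate medians over at least 3 cells.

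The groups, tests, gene lists, cell type markers, named-gene rule and first set of alternatives were fixed before the data were examined. The rule named the targeted gene, up to 12 genes that rose and 12 that fell with the smallest adjusted p (6 and 6 within a cell state) and a group mean of 10 CPM or more, and of each list up to 4 members past the threshold or, if fewer than 2 passed, the 2 most abundant. Cd86, Cd83, Gzma, Mlana and the other list members given above come from the list part of it. Xcr1, Txndc17, Ccl5 and Il12b over all cells, Gbp2, Psme1, H2-T23, H2-K1, Pdlim4, S100a6, Irf7, Ccr7, Fscn1 and Ccl22 within mature cells, and Irf1, Ikbkb, Txndc17 and Xcr1 within immature cells were chosen after their values were seen. Alternatives were DESeq2 1.42.0, upper-quartile factors, no filter on low counts, limma-trend with cells weighted equally, only the plates compared, all 5 control plates together, equal weights of the states, other minimum numbers of cells, other clustering resolutions, and each plate left out in turn. Added after seeing the data were cDC1-like cells only, genes in at least 10% of cells, the fibroblast-rich control plate and the Irf1-deleted plate with the fewest genes left out, the genes per cell as a covariate, the 8-week mice only, and the second clustering.

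The fits were tested on simulated counts with the means, depths and spread of these plates. For the Irf1 comparison over all cells edgeR recovered 16 of 100 genes changed 4-fold and 77 of 100 changed 16-fold among 14799 genes, with 2 false calls, and DESeq2 recovered 42 and 97 with 253 false calls. For the Ikbkb comparison edgeR recovered 2 and 32 of 100 among 14849 genes with 0 false calls, and DESeq2 made 510 false calls. For the difference of responses edgeR recovered 0 and 18 of 100 among 14849 genes. Within mature cells edgeR recovered 17 and 46 of 100 among 6058 genes with 12 false calls, and within immature cells 9 and 53 among 10105 genes with 10. In simulated plates with no list shifted, camera with the preset correlation called 1 of 22 lists for the Irf1 and 0 for the Ikbkb comparison. Simulated genes varied independently of each other. In the Irf1 comparison the estimated correlation was 0.48 for the type I interferon list and 0.37 for S phase. The simulated counts therefore cannot tell how often the preset correlation gives false calls in the real plates.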

Results

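Single cells sorted as type 1 conventional dendritic cells (cDC1) were profiled from YUMM1.7 melanomas grown under the skin of female mice. Each of the 14 samples was 1 plate of cells from 1 tumour of 1 mouse. The labels name 4 genotypes. Irf1_FF (4 plates, 165 cells) and Ikbkb_FF (1 plate, 34 cells) are called the Irf1 and Ikbkb controls here. Irf1_dXCR1 (5 plates, 223 cells) and Ikbkb_dXCR1 (4 plates, 133 cells) are called Irf1-deleted and Ikbkb-deleted. Irf1 encodes an interferon-responsive transcription factor, and Ikbkb the kinase IKKβ of the canonical NF-κB pathway. The comparisons ask how tumour cDC1 differ when either gene is targeted. The plates held 18 to 59 cells and 2810321 to 10120557 unique molecular identifiers (UMIs), with a median of 143476 UMIs and 1578 genes per cell. Mice of both Irf1 groups were 6 weeks old. The Ikbkb control mouse and 2 Ikbkb-deleted mice were 8 weeks old, and the other 2 Ikbkb-deleted mice were 6 weeks old.

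The targeted transcripts were lower on average in the deleted plates, but no difference passed its test. Irf1 (chromosome 11, 53770014 to 53778374, build GRCm38) had 342 ± 100 counts per 1000000 UMIs (CPM; SD, n = 4) in control plates and 228 ± 108 (n = 5) in Irf1-deleted plates, a log2 fold change of -0.59 ± 0.38 (SE; edgeR adjusted p = 0.685). Control plates ranged from 200.5 to 435 CPM of Irf1 and Irf1-deleted plates from 98.2 to 337, so the groups overlapped. In immature cDC1 alone Irf1 stood at 263 ± 128 CPM in control plates (n = 3) and 40.9 ± 65.3 in Irf1-deleted plates (n = 3; edgeR adjusted p = 0.681). In mature cells the transcript was still plentiful, at 820 ± 176 CPM in control and 506 ± 201 in Irf1-deleted plates (n = 3 each; adjusted p = 0.655). Ikbkb (chromosome 8, 22659212 to 22706589) had 291 CPM in its 1 control plate and 110.8 to 308.5 CPM in the 4 Ikbkb-deleted plates (log2 fold change -0.28 ± 0.58, adjusted p = 1). Among cDC1-like cells alone that value for Ikbkb was 0.04. The reads came from the 5′ end of transcripts, so they say nothing about exons deleted further along, and these levels do not check the labels.

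The cells fell into 12 clusters, which were grouped by marker genes into states called cDC1-like here and other cells. Immature cDC1-like cells (170 cells) were named by Xcr1, Clec9a, Cadm1 and other cDC1 genes, each found in 70.3% of these cells on average. A cluster of 38 cells among them had the DNA replication genes Mcm2, Gins1, Chaf1b and Dscc1 among its 10 top genes, which were chosen after their values were seen. Mature dendritic-like cells (131 cells) were named by Ccr7, Fscn1, Ccl22 and other genes of migrating, antigen-presenting dendritic cells, each found in 72.8% of them on average. A further 43 cells were interferon-stimulated and 27 were proliferating. These 4 states together made up 66.8% of all cells. The remaining cells were macrophage-like (56 cells), fibroblast- or endothelial-like (41) and T cell-like (13), beside clusters 4 (52 cells) and 11 (22), which stayed unnamed. The immature cDC1 markers were each found in 15.6% of mature cells on average, against 16.5% of macrophage-like and 38.0% of cluster 4 cells. Median XCR1 staining on the arcsinh scale was 8.71 in immature, 8.19 in mature, 7.38 in interferon-stimulated and 7.04 in macrophage-like cells. These markers alone therefore do not show that the mature cells are cDC1.

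The shares of these states did not separate the Irf1 groups. Mature cells made up 26.3 ± 15.1% of cells in control plates (SD, n = 4) and 22.4 ± 2.22% in Irf1-deleted plates (n = 5; exact permutation p = 0.611, two-sided). Immature cells made up 31.5 ± 9.70% and 25.9 ± 8.72% (exact permutation p = 0.389). The interferon-stimulated state held 2.01 ± 1.40% of control cells and 8.98 ± 8.29% of Irf1-deleted cells (exact permutation p = 0.159). Proliferating cells held 6.84 ± 3.36% and 2.86 ± 3.98% (exact permutation p = 0.151). After adjustment over the 9 states and unnamed clusters the smallest p was 0.583, where this design could reach 0.00794 before adjustment. Without control replicate 1 the mature share was 33.5% in control plates (exact permutation p = 0.0179, adjusted p = 0.161). In the Ikbkb control plate 58.8% of cells were immature (exact binomial 95% interval 40.7 to 75.4%) and 14.7% mature (4.95 to 31.1%). Among Ikbkb-deleted plates the immature share ran from 13.7 to 65.4% and the mature share from 7.69 to 33.3%. With 1 control plate an exact permutation test cannot give a p under 0.2.

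**Figure D1:**
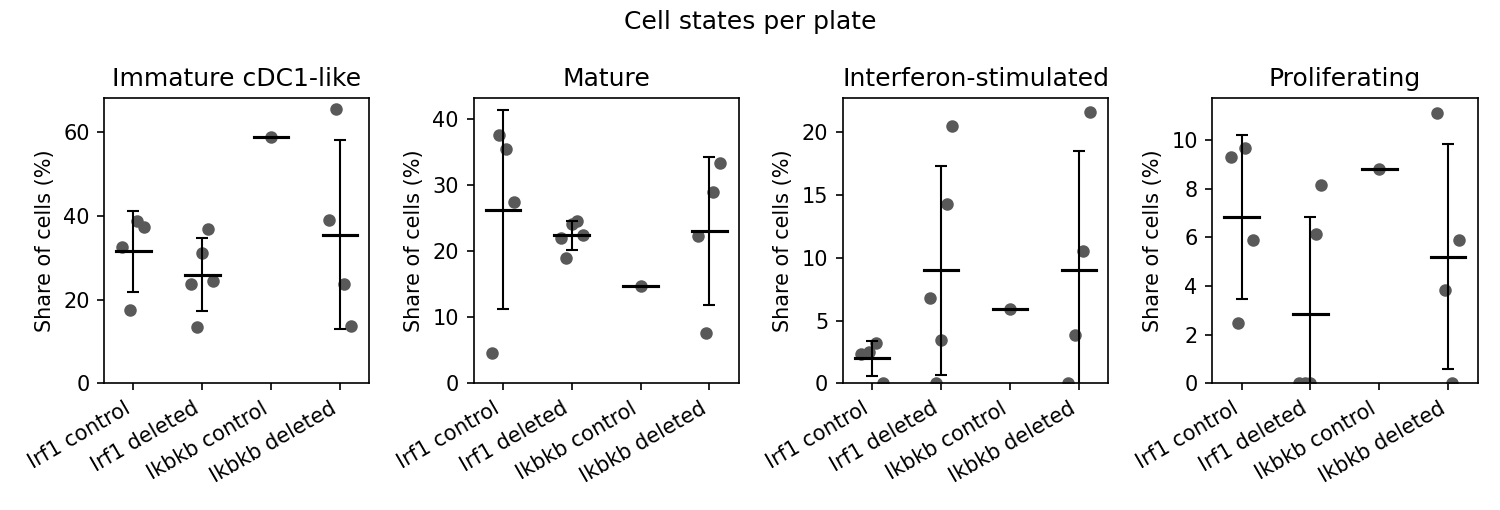
Share of cells in the 4 cDC1-like states (y axis, percent of the plate's cells) by genotype. Points are plates, lines are means and bars are SDs, which end at the axis where they would pass below 0. Interferon-stimulated cells reached 8.98% on average in Irf1-deleted plates and 2.01% in controls, with overlapping plates.

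Mature cells of Irf1-deleted plates had lower expression of Txndc17, Ccl5 and Il12b. Txndc17, a thioredoxin-like protein gene (chromosome 11, 72207547 to 72210015), fell from 2209 ± 314 to 395 ± 85.2 CPM (SD, n = 3 plates each with at least 10 mature cells), a log2 fold change of -2.48 ± 0.28 (edgeR adjusted p = 0.00839). It was the single gene that passed in that comparison. With a minimum of 5 mature cells, a setting fixed in advance as the second choice and given this place after its result was seen, 3 control and 5 Irf1-deleted plates entered. There Ccl5, a chemokine that draws in T cells and NK cells (chromosome 11, 83525778 to 83530518), fell from 3228 ± 1108 to 636 ± 427 CPM (log2 fold change -2.34 ± 0.27, adjusted p = 1.62e-10). Il12b, which encodes the p40 subunit of the interleukins IL-12 and IL-23 (chromosome 11, 44400063 to 44414033), fell from 3518 ± 1185 to 1449 ± 413 CPM (-1.28 ± 0.23, adjusted p = 5.4e-04). The adjusted p values of Ccl5 and Il12b rest on a spread shared with the Ikbkb plates. With only the Irf1 plates in the fit, edgeR gave adjusted p = 0.446 for each.

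The 9 genes past the threshold in those 8 plates were 6 that fell and 3 that rose. Txndc17 (log2 fold change -2.91), Bcl2l14 (-3.08), Glipr2 (-1.45) and the interferon-inducible noncoding RNA AW112010 (-1.31) fell with Ccl5 and Il12b, and in each of these 6 genes all 5 Irf1-deleted plates lay below all 3 control plates. Gngt2, a G protein subunit gene, rose from 63.1 ± 56.3 to 738 ± 414 CPM. Il1r2, a decoy receptor for interleukin 1, had no UMI in mature cells of the 3 control plates and 282 ± 238 CPM in Irf1-deleted plates, and Spic went from 0.166 ± 0.287 to 297 ± 302 CPM. Of other maturation genes, 3 chosen after their values were seen did not pass. Ccr7 stood at 3644 ± 904 and 3780 ± 610.5 CPM and Fscn1 at 831 ± 348 and 705 ± 208, while Ccl22 was lower on average, at 3322 ± 1786 and 2368 ± 249.5 (edgeR adjusted p of 1, 1 and 0.516). An exact permutation test of log2 CPM gave p = 0.0179, the smallest these 8 plates allow, for Ccl5, Il12b, Glipr2 and Gngt2, genes chosen after their values were seen, which restates the separation they were selected for in the same plates. The exact permutation p was 0.0357 for AW112010 and Spic, 0.0893 for Txndc17 and Bcl2l14, and 0.107 for Il1r2.

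**Figure D2:**
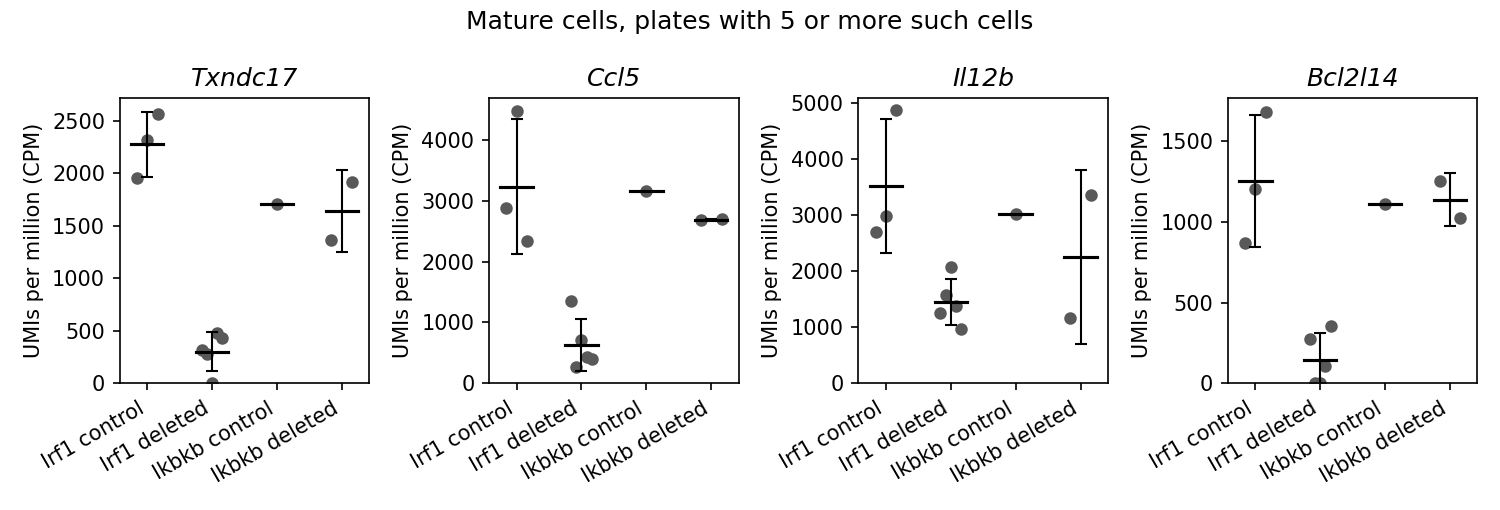
Expression of 4 genes in mature cells (y axis, CPM of the UMIs summed over a plate's mature cells) by genotype, in plates with at least 5 such cells. Points are plates, lines are means and bars are SDs. All 5 Irf1-deleted plates lie below all 3 Irf1 control plates for Txndc17, Ccl5, Il12b and Bcl2l14.

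The calls depended on the plates in the fit and on the tool. With only the 8 Irf1 plates in the fit, edgeR called 0 of these genes (220 at an unadjusted p under 0.05), although the log2 fold change of Ccl5 was -2.35 and that of Txndc17 -2.92. DESeq2 called 112 genes in the 8 plates, 2 of them among the 9 (Il1r2 and Spic). In the comparison of 3 against 3 plates DESeq2 called 105, and Txndc17 lost its edgeR call when control replicate 3 (adjusted p = 0.101) or 4 (0.0726) or Irf1-deleted replicate 4 (0.0829) or 5 (0.207) was left out. Ccl5 and Il12b are also among the markers that named the mature state. With the cells clustered without the 9 genes and the IRF1 target list, all 9 passed again. Of the 9 genes, 4 lie on chromosome 11 with Irf1, a chromosome that holds 8.56% of the genes tested (Fisher's exact p = 0.00472). That test was not fixed in advance. It treats genes called in the same plates as independent, so its p does not show an effect of the chromosome. Gngt2 rose, while Txndc17, Ccl5 and Il12b fell. In immature cells the log2 fold changes of these 4 were 0.51 ± 0.47 (Txndc17), 0.63 ± 1.62 (Gngt2), -0.47 ± 3.22 (Il12b) and -6.81 ± 3.43 (Ccl5).

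Camera with the preset correlation called genes of the interferon-γ response and IRF1 targets lower as a group in mature cells of Irf1-deleted plates. Of 41 measured members 32 were lower (camera adjusted p = 1.05e-04 with the preset correlation, and adjusted p = 0.747 with an estimated correlation), and 0 passed over all genes or adjusted over the list alone. By fry the list, which includes Irf1 itself, had adjusted p = 0.810. Among members chosen after their values were seen, Gbp2, an interferon-induced GTPase, stood at 486 ± 97.3 CPM in control plates and 67.0 ± 61.4 in Irf1-deleted plates (n = 3 each), and Psme1, a subunit of the proteasome activator, at 1596 ± 373 and 876 ± 187 (adjusted p of 0.655 for both). With at least 5 mature cells per plate the Gbp2 difference was smaller, at 500.6 and 156 CPM (3 and 5 plates; adjusted p = 0.516). Of 23 genes for presentation on MHC class I, 18 were lower (camera adjusted p = 0.00913, and adjusted p = 0.747 with an estimated correlation), and 1 passed adjusted over the list alone, H2-T23, a nonclassical class I gene, chosen after its values were seen. H2-T23 stood at 1124 ± 231 and 423 ± 163 CPM and H2-K1, a classical class I molecule, at 3082 ± 463 and 2224 ± 182. The class I and interferon-γ lists share Tap1, Tap2, Tapbp, Psmb8, Psmb9, Psmb10, Psme1, Psme2 and Nlrc5, so their calls are not independent, here or in other sets of cells. The maturation list (26 of 42 lower, adjusted p = 0.452) and the NF-κB list (14 of 32 lower, adjusted p = 0.716) did not pass, nor did the chemokine list (10 of 18 lower, adjusted p = 0.362), though in each of these 3 lists Ccl5 and Il12b passed adjusted over the list alone. The median of the NF-κB list was above 0 while camera placed it lower. All other lists had an adjusted p of 0.362 or more.

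In immature cDC1 3 Irf1-deleted plates were compared with 3 control plates. Camera with the preset correlation called the type I interferon list higher and the MHC class I list lower in Irf1-deleted plates. Of 42 interferon-stimulated genes 31 were higher, among them Ifitm3 at 888 ± 123 CPM in control and 1771 ± 310 in Irf1-deleted plates (log2 fold change 1.00 ± 0.22, adjusted p = 0.681). Of 23 class I genes 21 were lower, with H2-D1 at 2440 ± 250.1 and 2182 ± 204 CPM, and 16 of 21 genes of the G2 and M phases were lower, with Hmgb2 at 285 ± 41.6 and 177 ± 54.2 CPM. Each of these 3 lists had a camera adjusted p of 8.68e-04 (adjusted p = 0.737, 0.594 and 0.594 with an estimated correlation). Interferon-γ response genes were lower (29 of 41) and cholesterol synthesis genes higher (14 of 16), both at adjusted p = 0.0195 and at adjusted p = 0.737 with an estimated correlation. The other lists had an adjusted p of 0.0531 or more. Adjusted over the list alone, Ifitm3 and the macrophage markers Csf1r (no UMI in control, 69.2 CPM in Irf1-deleted plates) and C1qa (100.9 CPM in control, no UMI in Irf1-deleted plates) passed, genes chosen after their values were seen, and over all genes edgeR called 0 (225 at an unadjusted p under 0.05, 385 by DESeq2).

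Over all sorted cells, camera with the preset correlation called the interferon-stimulated and MHC class II lists higher and cell cycle lists lower in Irf1-deleted plates. Of 44 type I interferon-stimulated genes 37 were higher (camera adjusted p = 1.88e-06), with Ifitm3 at 1349 ± 190.5 CPM in control plates (n = 4) and 2136 ± 579 in Irf1-deleted plates (n = 5). Of 28 S phase genes 26 were lower (6.6e-06), with Pcna at 240.3 and 190.3 CPM, although Rfc2 stood at 172.8 and 196.1 CPM, and of 28 G2 and M phase genes 25 were lower (4.14e-04), with Hmgb2 at 349 and 254 CPM. Of 13 MHC class II genes 12 were higher (0.00114), with H2-Ab1 at 3195 and 4298 CPM and Cd74, the invariant chain, at 3804 and 4767 CPM. The maturation list (23 of 43 higher, 4.14e-04), NF-κB targets (17 of 33, 0.0116) and costimulation genes (10 of 17, 0.0436) were also called as higher; Cd86 stood at 483 and 858 CPM. These 3 calls depended on single plates. Without control replicate 1 the maturation list was called as lower (median log2 fold change -0.32, adjusted p = 3.25e-05), and the NF-κB (0.124) and costimulation (0.613) lists also turned lower without passing. The NF-κB list also lost its call without control replicate 4 (0.0565) or Irf1-deleted replicate 1 (0.0870), and the costimulation list without these (0.0565 and 0.0917) or Irf1-deleted replicate 5 (0.0871). All of these lists had adjusted p = 0.614 with an estimated correlation, and 0 of their members passed over all genes or adjusted over the list alone.

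Lists for tissue handling and for other cells in the sort also moved. Dissociation and heat-shock genes were called as higher (adjusted p = 0.00561), though 10 of 17 members were lower in the edgeR fit and the call was lost without control replicate 3 (0.146), and NK cell markers as lower (5 of 5, adjusted p = 0.0499; 4 of 5, Ncr1, Klrb1c, Prf1 and Gzma, chosen after their values were seen, passed adjusted over the list alone), each at adjusted p = 0.614 with an estimated correlation. The NK difference came from control replicate 2: Ncr1, Klrb1c and Prf1 had UMIs in that plate alone, and Gzma, of cytotoxic cells, reached 158.5 CPM there, with 40.7 ± 78.6 over the control plates and no UMI in Irf1-deleted plates. Without that plate the NK list had too few kept genes, and its call was lost without Irf1-deleted replicate 1 (0.0654), 4 (0.0783) or 5 (0.0972). The other 13 lists had a camera adjusted p of 0.0539 (cDC1 identity, and chemokines and cytokines) or more: cholesterol 0.116, T cells 0.355, macrophages 0.384, plasmacytoid dendritic cells 0.436, glycolysis and hypoxia 0.477, interferon-γ response 0.493, cDC2 0.554, apoptosis 0.739, mitochondrial transcripts 0.755, and MHC class I and fibroblasts 0.981. The MHC class I list was unstable: it was called as lower without control replicate 1 (0.0194), 3 (0.0151) or 4 (0.00816) or Irf1-deleted replicate 2 (0.0120) or 3 (0.0421), and as higher without Irf1-deleted replicate 5 (0.0348). Leaving out single plates also brought calls of the chemokine list (higher, in 4 of 9 cases), and in 1 or 2 cases of the cDC1 identity and cholesterol lists (higher) and the mitochondrial, T cell, macrophage and fibroblast lists (lower). B cell, neutrophil and melanoma lists had too few kept genes; Ighm stood at 259 ± 140 and 96.2 CPM, Csf3r at 9.71 and 2.23, and Mlana at 4.89 in control plates with no UMI in Irf1-deleted plates.

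For single genes over all cells, edgeR called 0 of 16203 (1272 at an unadjusted p under 0.05), limma-trend 0 and DESeq2 100, of which 83 were found in under 5% of cells. Among cDC1-like cells alone 5 lists passed: S phase (1.08e-07) and G2 and M phase (3.07e-11) lower, type I interferon (6.09e-04) higher, and MHC class I (0.00385) and interferon-γ response (0.0343) lower. With an estimated correlation none did (adjusted p = 0.708 for the cell cycle and MHC class I lists and 0.799 for both interferon lists). The MHC class II list lost its call among cDC1-like cells even with the preset correlation (camera adjusted p = 0.105). With the genes detected per cell as a covariate the interferon (6.66e-11), MHC class II (1.32e-04), S phase (7.33e-05) and G2 and M phase (7.33e-05) lists passed, while the maturation, NF-κB, costimulation, stress and NK cell lists did not. Plates fell into 4 with many genes per cell (medians 1981 to 2241) and 5 with few (705 to 1577), 2 control plates in each. The mean log2 CPM of the interferon list differed by 0.83 within the gene-rich and 0.12 within the gene-poor plates, the S phase list by -0.67 and -2.41, and the G2 and M phase list by -0.03 and -2.40. No list level passed an exact permutation test across the 9 plates (adjusted p = 0.992 for each). Before adjustment the exact permutation p was 0.349 for the interferon list, 0.222 for MHC class II, 0.103 for S phase and 0.0635 for G2 and M phase.

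In Ikbkb-deleted plates S phase genes and T cell markers were lower than in the 1 control plate, which could not be left out. Calls of 5 other lists depended on which Ikbkb-deleted plates were used. Of 28 S phase genes 24 were lower (camera adjusted p = 2.95e-04), with Pcna at 309 CPM in the control plate and 166 CPM on average in 4 Ikbkb-deleted plates. Of 44 type I interferon genes 40 were higher (0.0338), with Ifitm3 at 744 and 1529 CPM, of 45 interferon-γ response genes 37 were higher (0.0412), with Psme2 at 1625 and 2078 CPM, and of 43 maturation genes 32 were higher (0.0412), with Cd63 at 281 and 566 CPM, although Cd83, a maturation marker, stood at 1596 and 1301 CPM. Stress genes were lower (15 of 17, 0.0412), with Hspa8 at 2579 and 2107 CPM. T cell markers were lower (7 of 9, 3.24e-05): Cd3d stood at 156 CPM in the control plate and at 32.0 CPM in Ikbkb-deleted plates. The T cell markers stayed lower among cDC1-like cells alone (4.99e-11, and adjusted p = 0.00489 with an estimated correlation), where the mean log2 CPM was 4.60 in the 1 control plate and -0.72 in Ikbkb-deleted plates, so the T cell-like cluster does not hold all of the difference. All Irf1 plates, control and deleted, stood between -1.10 and 0.27 in these cells. A low level was therefore also present without Ikbkb deletion, in the Irf1 plates. The high value is thus that of the 1 Ikbkb control plate, and a trait of that mouse cannot be told apart from the deletion. Mitochondrial transcripts were called as lower (0.0338) with 3 of 7 higher and 4 lower. With an estimated correlation these 7 lists had adjusted p = 0.833 (T cells), 0.887 (S phase, interferon-γ, stress and mitochondrial) and 0.909 (type I interferon and maturation).

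Macrophage markers (adjusted p = 0.0867), cDC1 identity (0.0700), cDC2 markers (0.0984), and cholesterol and costimulation lists (0.130 each) did not pass, nor did MHC class I (0.390), glycolysis (0.395), MHC class II, chemokines (0.633 each), apoptosis (0.770), NF-κB, NK cell, plasmacytoid and fibroblast lists (0.878 each) or G2 and M phase (0.983). Nfkbia, the NF-κB inhibitor and target, stood at 695 CPM in the control plate and 706 in Ikbkb-deleted plates, and Irf1 at 109.7 and 237 CPM (log2 fold change 1.11 ± 0.68, edgeR adjusted p = 1). Adjusted over the list alone, 1 gene passed in each of 5 lists, chosen after their values were seen: Il18bp (interferon-γ), Pdcd1lg2 (costimulation), Ube2c (G2 and M phase) and Col3a1 (fibroblast), all higher, and Stard4 (cholesterol), lower. edgeR called 0 of 16203 genes (707 at an unadjusted p under 0.05), limma-trend 288 and DESeq2 1177, of which 277 and 703 were found in under 5% of cells. With plates of 8-week mice alone 2 lists passed, S phase (0.0101) and T cell markers (0.0150), and the same number passed without Ikbkb-deleted replicate 3 or 4, both of 6-week mice. Without replicate 3 the type I interferon, interferon-γ and maturation lists each stood at adjusted p = 0.205, and without replicate 4 at 0.488, 0.421 and 0.111; 2 of the 4 Ikbkb-deleted plates lay above the control in mean log2 CPM of either interferon list. The stress list lost its call without replicate 1 (0.236), 3 (0.116) or 4 (0.0649), and the mitochondrial list without any one of the 4 plates (0.235 to 0.881).

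Within immature cells 1 control and 1 Ikbkb-deleted plate had at least 10 cells. edgeR called 0 genes there (267 at an unadjusted p under 0.05; DESeq2 547), with the spread taken from the Irf1 plates. Differences between the mice cannot be told apart from the deletion with 1 plate each, so no list difference is reported for Ikbkb in this state. In mature cells only a minimum of 5 cells allowed a comparison, of 1 control plate with 5 mature cells and 2 Ikbkb-deleted plates. edgeR called 84 genes in it, which are not taken as differences because the control is 5 cells of 1 mouse.

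The difference between the responses to the 2 deletions was tested directly. It rests on 1 Ikbkb control plate, assumed to vary like the others, and single plates were not left out in turn for these lists. Interferon-γ response genes were called as higher after Ikbkb than after Irf1 deletion relative to their own controls (36 of 45, camera adjusted p = 0.0453). Mean log2 CPM of that list was 5.63 in the Ikbkb control plate, of an 8-week mouse. It was 4.59 and 5.34 in Ikbkb-deleted plates of 8-week mice, and 6.91 and 7.19 in those of 6-week mice. The higher levels thus came from the 6-week mice alone, and age was not held fixed. Stress genes (15 of 17, adjusted p = 0.0154), cDC1 identity genes (15 of 20, 0.0453) and T cell markers (7 of 9, 0.0453) were lower, and macrophage markers higher (13 of 15, 0.0453). All 5 stood at adjusted p = 0.831 with an estimated correlation, and the other lists had an adjusted p of 0.0773 or more. Adjusted over the list alone Il18bp, Ube2c and Col3a1 passed, chosen after their values were seen. For single genes edgeR called 0 of 16203 (543 at an unadjusted p under 0.05), limma-trend 232 and DESeq2 900. Txndc17 had a difference of responses of 1.93 ± 0.77 on the log2 scale over all cells (adjusted p = 1.00).

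Depth did not separate the Irf1 groups. Median UMIs per cell were 143618 ± 45215 in control plates (SD, n = 4) and 135971 ± 38056 in Irf1-deleted plates (n = 5; exact permutation p = 0.810). Median genes per cell were 1594 ± 586 and 1560 ± 607 (exact permutation p = 0.960). With cells thinned to 50000 UMIs, genes per cell were 1622 ± 417 and 1447 ± 527 (exact permutation p = 0.595), which left out 34 control and 26 Irf1-deleted cells.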

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

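The tests of Txndc17 with other clusters or with a covariate, those of the lists by cell type and by genes per cell, and the test of a shared allele were chosen after the result was seen. Of 63 groups of 4 or 5 plates examined for a plate far from the others 2 held one, where chance gives about 1 in 20. Unnamed cluster 4, whose cells had a median of 725.5 genes, made up 48.6% of Irf1-deleted replicate 2, far above the other 4 plates. T cell-like cells made up 16.7% of Ikbkb-deleted replicate 1, which is 3 of its 18 cells. Against 1 Ikbkb control plate, responses to the 2 deletions were called as different for the lists of cDC1 identity, interferon-γ response, macrophage markers and T cell markers (camera adjusted p = 0.0453 each) and for stress genes (adjusted p = 0.0154), none of which passed with an estimated correlation (adjusted p = 0.831). Mouse age was not held fixed in these comparisons.

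Protein stainings recorded during the sort differed before adjustment between the Irf1 groups. In immature cells of Irf1-deleted plates CD11c was higher by 0.691 on the arcsinh scale (exact permutation p = 0.0159) and CD64 by 3.09 (p = 0.0397). Control plates varied widely in that CD64 value (2.89 ± 4.90 against 5.98 ± 0.679 in Irf1-deleted plates). In mature cells CD64 went the other way, by -3.93 (exact permutation p = 0.357). In mature cells CD11c was higher by 0.930 (exact permutation p = 0.0179), CD45 by 0.472 (p = 0.0179) and the lineage stain by 2.33 (p = 0.0357). None of the 14 stainings tested passed adjustment, the smallest adjusted p being 0.0625.

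Chance was examined by splitting the Irf1 plates in other ways. Over all cells 39 of 100 splits gave at least the real 9 lists, with a highest other count of 17, so chance cannot be excluded for the lists. A camera p at least as small as the real one, in either direction, came in 14 of 100 splits for the interferon list. For S phase it came in 7 and for G2 and M phase in 10, the real split included. For genes the real count was 0, which every split matches by design (100 of 100, with a highest other count of 1), so that test decides nothing. The split by genes per cell gave 11 lists, more than the genotype. In immature cells the real count was 0 and the highest other 0 (10 of 10 splits), and in mature cells with 3 against 3 plates the real count was 1 and the highest other 0 (1 of 10); 10 splits are too few for a share under 0.05. In mature cells of plates with at least 5 such cells 1 of 56 splits, the real one, gave 9 genes, with a highest other count of 8. That share is under 0.05, but the setting was given its place after its result was seen and the next count is close, so chance is not taken as excluded.

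Lower Txndc17 and Ccl5 in mature Irf1-deleted cells could come from assigning cells to the state by the same genes, from unequal shares of the 2 mature clusters, or from plates with few genes per cell. The sizes of the fold changes argue against each, though in few plates. Txndc17 kept a log2 fold change of -2.50 with cells clustered without the tested genes and of -2.63 with genes per cell as a covariate (edgeR adjusted p = 0.00739 and 0.0456 in 3 against 3 plates). Within cluster 7 alone, in 3 against 4 plates, the log2 difference of Ccl5 was -2.15 (SE 0.426, exact permutation p = 0.0571). That of Txndc17 was -4.59 (SE 2.155, exact permutation p = 0.0857), so neither passed there. In the 8 plates with at least 5 cells the call of Txndc17 was lost with the covariate (-2.91 ± 0.46 before, -3.12 after). It was also lost in the fit of the same 8 Irf1 plates without the covariate (-2.92). The smaller fit alone was thus enough to end the call, and what the covariate adds cannot be told. Lower Txndc17 and Ccl5 in mature cells of Irf1-deleted plates may be biological, as a hypothesis found and tested on the same cells, or chance. The chromosome that 4 of the 9 genes share with Irf1 stays open and was not tested further.

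The higher interferon list and lower cell cycle lists of Irf1-deleted plates could reflect other cell types in the sort or the genes detected per cell. In cDC1-like cells the 3 lists stayed past the threshold with the preset correlation (camera adjusted p = 6.09e-04 for the interferon list). None passed with an estimated correlation (adjusted p = 0.708, 0.708 and 0.799). Their levels there gave exact permutation p of 0.667 (interferon), 0.103 (S phase) and 0.0635 (G2 and M phase). Other cell types alone are thus argued against only under the preset correlation. The cDC1-like cells include the interferon-stimulated and proliferating states, named by many of the same genes. These states held 3.16% and 10.7% of cDC1-like cells in control plates, and 12.7% and 3.66% in Irf1-deleted plates. State shares were therefore not held fixed. For S phase the level differed by -0.67 ± 0.32 (SE) within the gene-rich and -2.41 ± 0.91 within the gene-poor plates, past its SE in both. The gene-rich set held 2 plates of each group, and the gene-poor plates still ran from 705 to 1577 median genes. Depth was thus not held fixed, and these values argue only weakly against it as the whole cause. Without the Irf1-deleted plate of the fewest genes, replicate 2, the S phase median went from -1.63 to -0.80 (camera adjusted p = 0.00119). For the G2 and M phase list the gene-rich plates gave -0.033, so the difference rests on the gene-poor plates and such a set of plates may explain it. For the interferon list the gene-rich plates gave 0.83, but among cDC1-like cells the gene-poor plates gave -0.46 ± 0.86, so depth and genotype cannot be told apart for it.

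XCR1 staining differed before adjustment in Irf1-deleted plates, by -1.03 in immature cells (9.27 ± 0.418 against 8.25 ± 0.545, exact permutation p = 0.0317, adjusted p = 0.0794). In mature cells it differed by -1.23 (exact permutation p = 0.0179, adjusted p = 0.0625). Neither difference passed adjustment. A stain or detector setting may account for part of the lower staining, as cells outside the cDC1-like states differed by -0.528 (exact permutation p = 0.421) and the gap between the differences in these and in immature cells was not resolved (p = 0.516). A lower Xcr1 transcript also goes with it: Xcr1 in immature cells had a log2 fold change of -0.92 ± 0.38 (edgeR adjusted p = 0.681). An allele at Xcr1 carried by both deletion lines is a candidate explanation that cannot be told apart from loss of Irf1, since Xcr1 had a log2 fold change of -1.45 ± 0.74 with Ikbkb deletion (edgeR adjusted p = 1).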

How the results depend on the processing

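Tests with cDC1-like cells only, genes in at least 10% of cells, 8-week mice, the 2 sets of plates, the second clustering, and combinations with at least 5 cells were chosen after the result was seen. Over all cells DESeq2 called 100 genes (Irf1), 1177 (Ikbkb) and 900 (difference), and limma-trend 288 and 232 for the last 2 comparisons. Genes in at least 10% of cells gave 4 (Ikbkb) and 4 (difference), 8-week mice 1, cDC1-like cells 1 (Ikbkb), and the 5 gene-poor Irf1 plates 1; the counts stayed at 0 under upper-quartile factors, no filter on low counts, cells with 500 or more genes, equal state makeup and without the fibroblast-rich and the most gene-poor Irf1 plate. Leaving out each plate gave 0 genes for Irf1 and Ikbkb and 0 to 1 for the difference (1 without Irf1_FF replicate 3). Lists went from 9 to 0 with an estimated correlation, 2 by fry and 5 in cDC1-like cells (Irf1), and from 7 to 0, 1 by fry and 2 in 8-week mice (Ikbkb); with each plate left out they numbered 8 to 13 and 2 to 9. In immature cells DESeq2 called 385 (Irf1) and 547 (Ikbkb), and leaving out plates gave 0 for Irf1. In mature cells the count of 1 became 105 by DESeq2, 9 with at least 5 cells, and 0 to 3 with plates left out (3 without Irf1_dXCR1 replicate 1). The count of 9 became 112 by DESeq2, 0 with only the Irf1 plates, 0 with the genes per cell as a covariate, and 6 to 17 with plates left out (6 without Irf1_FF replicate 4, 17 without replicate 2, 15 without replicate 3, and 15 without Irf1_dXCR1 replicate 1). Txndc17, Ccl5, Bcl2l14 and AW112010 were called in 8 of 8 of those leave-outs, Il12b, Glipr2 and Gngt2 in 7, Spic in 4 and Il1r2 in 3. Irf1 in its own deletion ranged from -0.77 to -0.39 (log2) and Ikbkb from -0.43 to -0.05, with 0.0392 in cDC1-like cells. No state share passed after adjustment in any setting run. Without Irf1_dXCR1 replicate 2 the interferon-stimulated share had an exact permutation p of 0.0286 (adjusted p = 0.257), and without replicate 5 its difference went from 6.97 to 4.12 percentage points. That share was 1.16% in control and 17.3% in Irf1-deleted gene-rich plates, and 2.86% and 3.41% in the gene-poor plates. The proliferating share differed by -0.449 percentage points in the gene-rich and -6.09 in the gene-poor plates. The Ikbkb difference in mature share ranged from 4.92 to 13.5 percentage points with plates left out, and was -0.910 against all 5 control plates. The causes of these changes were not tested. A minimum of 20 cells left too few plates and gave no value, and with 1 plate per group no plate could be left out of the Ikbkb comparison within immature cells. No paired analysis was possible because replicate numbers follow the order of the accessions and pair no plates. Simulated plates with the estimated spread returned 16 of 100 genes changed 4-fold over all cells (Irf1), and 96 of 100 with 0.1 of that spread.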

Other observations

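All tests in this part were chosen after the result was seen. Within plates, mature cells stained higher for MHC class II than immature cells in 8 of 10 plates (mean difference 1.20 ± 1.04 on the arcsinh scale, exact permutation p = 0.0117) and lower for XCR1, which was higher in only 1 of 10 plates (-0.596 ± 0.714, exact permutation p = 0.0195). CD11b was also higher in mature cells, in 8 of 10 plates (3.96 ± 4.91, exact permutation p = 0.0215). Adjusted over 21 tests each of these stood at 0.150. Mature cells fell into cluster 7 (88 cells) and cluster 8 (43 cells), and cluster 7 held 69.0% of mature cells of Irf1 control plates, 76% of Irf1-deleted plates, and 55.9% of Ikbkb-deleted plates.

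Other genes in mature cells differed between the Irf1 groups without passing adjustment in 3 against 3 plates. Pdlim4 stood at 764 ± 215 CPM in control and 156 ± 51.4 in Irf1-deleted plates, S100a6 at 90.9 ± 41.0 and 610 ± 56.4, and Irf7, a transcription factor of the type I interferon response, at 447 ± 161 and 1131 ± 297 (edgeR adjusted p of 0.307, 0.307 and 0.655). In 3 control and 5 Irf1-deleted plates with at least 5 mature cells the differences were smaller: Pdlim4 stood at 789.8 and 285 CPM, S100a6 at 94.2 and 576.5, and Irf7 at 462 and 867 (adjusted p of 0.516, 0.439 and 0.516). In immature cells Ikbkb stood at 125 ± 27.8 CPM in control and 326 ± 107 in Irf1-deleted plates (edgeR adjusted p = 0.681).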
